A study of Homo sapiens with 4 samples.

How the data were processed

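RNA of human primary alveolar epithelial cells, grown on poly-L-lysine in a commercial alveolar epithelial medium, was sequenced after 48 h with phosphate-buffered saline (PBS, the vehicle) or cigarette smoke extract (CSE, the soluble part of smoke drawn through a liquid) in the medium. There were 4 libraries, 2 per group, and the labels give the group and a replicate number for each. The concentration of the extract and the origin of the cells are not given in the sources used here.

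The deposited file holds raw read counts per gene, 1 column per library, with no normalization. Per the submitters' processing notes, reads were aligned with STAR to hg38 and counted with featureCounts 1.5.0-p1. The STAR version, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes are identified by symbol, and the table gives the exon coordinates of each on hg38. Genes with near-identical copies, such as HSPA1A and HSPA1B, HSPA6 and HSPA7, AKR1C1 and AKR1C2, the metallothioneins, the ferritins with their pseudogenes and the histone genes, can exchange or lose reads at the counting step, so their separate values are uncertain. Reads of overlapping or antisense genes cannot be told apart without a known strand setting.

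From the counts, 14359 of the 26485 genes were kept by the filterByExpr defaults of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total count 15), and 20330 genes had at least 1 count in any library. Libraries were scaled by the trimmed mean of M-values (TMM). CSE was compared with PBS by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with treatment as the only term, two-sided, with Benjamini-Hochberg adjustment over the 14359 genes, and a gene was said to have risen, fallen or changed at an adjusted p under 0.05. Fold changes are the fitted CSE over PBS ratios, given on the log2 scale with a standard error (SE). That SE was worked back from the test, as the log2 fold change divided by the square root of its F statistic. For genes with few counts in a group, such as HSPA7, it is narrower than the counting interval and understates the uncertainty. Expression levels are CPM, counts scaled by TMM-adjusted library totals, computed here. All mean ± SD values are over n = 2 libraries.

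Before the data were examined, 35 gene lists with 626 genes were fixed for the cell type and the treatment, and 613 of the genes were in the table, 6 of them under an older symbol. Lists with at least 3 tested members (34 of 35) were tested against all other genes with camera (limma 3.58.1) at its preset correlation of 0.01 and again with an estimated correlation, and with fry, which tests the members of a list by themselves, for a net direction and for changes in either direction (mixed). List p-values were adjusted over the 34 lists. The genes to name were also fixed by a rule at that time. They are the 8 with the largest rise and the 8 with the largest fall among genes past the threshold, with an average log2 CPM of at least 3 and no overlap of the groups, leaving out unnamed and antisense transcripts, and the 3 members of each list with the smallest p. Other members of a list or family that are named were chosen after their values were seen. The values of some genes that the rule selects or that belong to a list are not reported here. Genes of the sex chromosomes that would reveal a donor's sex are not shown.

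The steps were tested on simulated data with 14359 genes drawn from the observed means and library totals. Of the genes changed in that simulation, 61.2% were recovered at 1.5-fold, 89.6% at 2-fold and 97% at 4-fold, and 9 unchanged genes were called, 4.74% of the calls. With no gene changed, 5 genes were called. Only a small share of the genes was changed in that simulation, whereas 60.4% of the tested genes were called changed in the data. Its shares of recovered genes and of wrong calls therefore need not hold for the real comparison. Total counts ran from 19978284 to 20824663 per library, so depth differed little between groups. No exact permutation test of 2 against 2 libraries can give a two-sided p below 0.333, so single values per library are given without a test.

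The results were recomputed with RLE size factors, with library totals alone, without a low-count filter, with a filter of CPM of at least 1 in 2 libraries, with DESeq2 1.42.0, with limma-voom, with the replicate number as a block, without the 10 most abundant genes and without each library in turn. Families of genes that share a symbol prefix were tested only after the data had been seen. Mitochondrially encoded genes and dose effects were not analysed here, so CPM and shares of counts are taken without those genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.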

Results

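Gene expression was measured by RNA sequencing in human primary alveolar epithelial cells, the cells that line the gas-exchange surface of the lung, to ask how 48 h of cigarette smoke extract (CSE) changes their transcripts relative to the vehicle PBS. The data comprise 2 PBS and 2 CSE libraries, with 20824663 and 19978284 counts in PBS and 20298243 and 20197343 in CSE. At least 1 count was found for 17434 and 17671 genes in the PBS libraries and for 18721 and 18751 in the CSE libraries, and the 10 most abundant genes of each library took 7.86% and 7.5% of its counts in PBS and 5.65% and 5.82% in CSE. Across genes, log2 CPM correlated at 0.993 between the PBS libraries, at 0.996 between the CSE libraries and at 0.943 to 0.947 between groups, and the first principal component, which separated the groups, held 89.7% of the variance. Counts of same-group libraries differed by more than sampling noise (chi-square per degree of freedom 9.31 in PBS and 3.45 in CSE), so all 4 were treated as separate samples. Nothing in the labels says that the replicates are separate cultures or donors, so all p-values here measure only the spread between these samples, which may be technical.

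Transcripts of epithelial and lung identity were measured in both groups. EPCAM, an epithelial adhesion molecule, stood at 439 ± 0.909 CPM in PBS and 461 ± 8.07 CPM in CSE (SD, n = 2), a difference that did not pass the test (edgeR adjusted p = 0.445; with library totals alone it did, at log2 0.25). Transcripts of NKX2-1, a lung lineage transcription factor, gave 362 and 462 counts in PBS and 462 and 499 in CSE. SFTPC, the surfactant protein most specific to type 2 cells, gave 1 and 0 counts in PBS and 4 and 8 in CSE, a ratio of 10.5 with a 95% counting interval of 1.56 to 450.

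After CSE, 14 of 15 heat shock genes and 21 of 26 NRF2 antioxidant targets rose, and 21 of 21 matrix genes and 24 of 27 mitosis genes fell. The inducible chaperone HSPA6 rose 460.5-fold (count ratio 457, 95% counting interval 320 to 678) and the small heat shock protein CRYAB 74.0-fold, HMOX1, which degrades heme, rose 30.6-fold, and the NRF2 target AKR1C1, an aldo-keto reductase, rose 17.9-fold. The matrix glycoprotein TNC fell by 4.87 ± 0.11 (SE) on the log2 scale, the collagen chain COL6A3 fell by 4.07 ± 0.13 and the proliferation marker MKI67 fell by 3.73 ± 0.17. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8671 of 14359 tested genes changed (60.4%), 4433 of them higher and 4238 lower in CSE. At least 2-fold changes were found for 2576 genes, 1383 higher and 1193 lower, and at least 4-fold changes for 714, 441 higher and 273 lower, while 3771 of the changed genes differed by less than 1.5-fold. Both CSE libraries lay on the same side of both PBS libraries for 11471 genes (79.9%), where chance gives 33.3%. The biological coefficient of variation was 6.61%.

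The split between rises and falls depends on the scaling. TMM left the median log2 fold change of all tested genes at 0.02, and 51.1% of the changed genes were higher in CSE. With library totals alone that median moved to 0.20, and 66.9% of the changed genes were higher, 5980 against 2960 lower. Changes are therefore relative to the other genes of a library, and the values given use TMM.

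**Figure D1:**
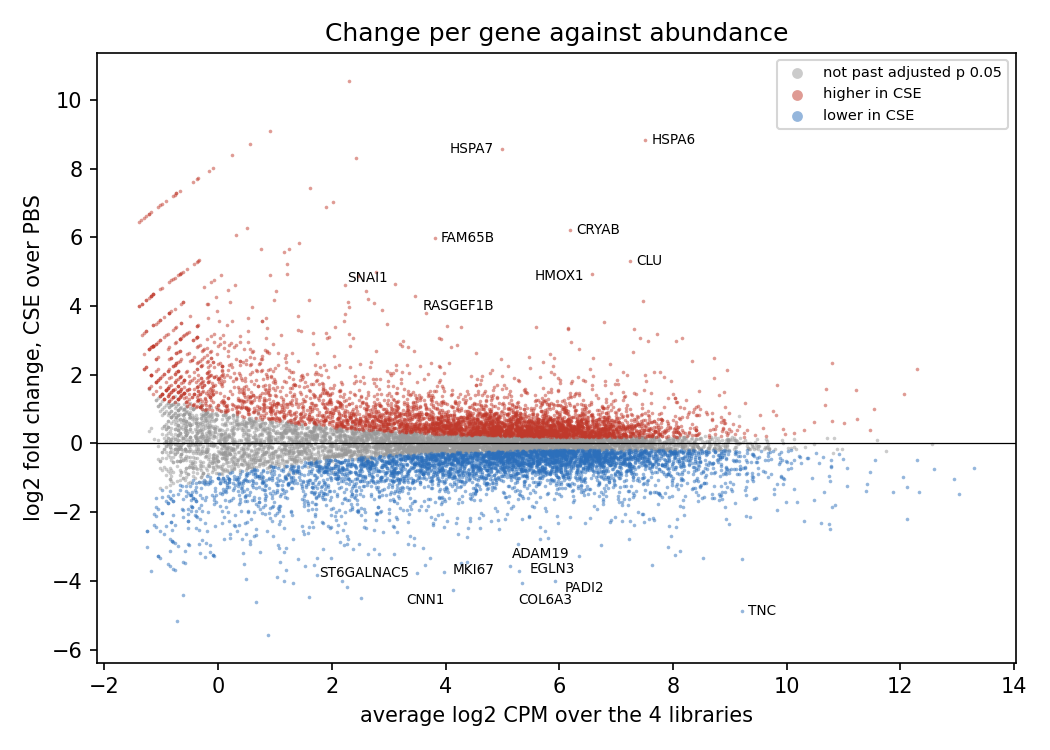
Each point is 1 of the tested genes, with its average log2 CPM over the 4 libraries on the x axis and its fitted log2 fold change, CSE over PBS, on the y axis; red and blue mark genes higher and lower in CSE at an adjusted p under 0.05 and grey the others. The labelled genes are the 8 largest rises and falls at an average log2 CPM of at least 3, from HSPA6 at 8.85 to TNC at -4.87, and the oblique lines at the left are genes with few or no counts in PBS, whose fitted values depend on the count added before taking logs.

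Among the genes named for the size of their rise, HSPA6 lies on chromosome 1 (hg38, 161524540 to 161526897, plus strand, 1 exon) and rose from 0.785 ± 0.451 to 363.5 ± 24.3 CPM (SD, n = 2; log2 8.85 ± 0.17 SE, adjusted p = 8.32e-13). Its PBS level rests on 9 and 21 counts, and its log2 fold change was 8.35 without PBS replicate 1 and 9.54 without PBS replicate 2. The near-identical neighbour HSPA7, annotated as a pseudogene (chromosome 1, 161606059 to 161608551), rose by 8.59 ± 0.21 from 3 counts in each PBS library (ratio 394 with a 95% counting interval of 181 to 1070). Reads may be shared between the pair at counting. CRYAB (chromosome 11, 111908620 to 111913213, minus strand) rose from 1.93 ± 0.497 to 143 ± 9.12 CPM. The extracellular chaperone CLU (chromosome 8, 27596917 to 27614811, minus strand) rose 39.9-fold to 295 ± 10.5 CPM. HMOX1 (chromosome 22, 35381067 to 35394214, plus strand) rose from 6.03 ± 0.690 to 185 ± 13.2 CPM (adjusted p = 2.09e-12). FAM65B rose 63.1-fold, SNAI1, a transcriptional repressor of epithelial genes, rose 25.1-fold to 15.9 ± 2.39 CPM, and RASGEF1B, a Ras-family exchange factor, rose 19.7-fold.

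Of the genes named for the size of their fall, TNC (chromosome 9, 115019576 to 115118257, minus strand) went from 1153 ± 135 to 39.5 ± 3.27 CPM (SD, n = 2; adjusted p = 3.04e-12). CNN1, a smooth muscle calponin (chromosome 19, 11538717 to 11550323, plus strand), fell by 4.25 ± 0.15 on the log2 scale, and COL6A3 (chromosome 2, 237324012 to 237414207, minus strand) went from 77.5 ± 9.39 to 4.60 ± 0.891 CPM. PADI2, which converts arginine in proteins to citrulline, fell by 4.02 ± 0.10, and ST6GALNAC5, a sialyltransferase, fell by 3.76 ± 0.16. MKI67 (chromosome 10, 128096661 to 128126204, minus strand) went from 29.7 ± 5.42 to 2.23 ± 0.0837 CPM. EGLN3, an oxygen-sensing prolyl hydroxylase, fell by 3.70 ± 0.11 and the metalloproteinase ADAM19 fell by 3.57 ± 0.11.

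**Figure D2:**
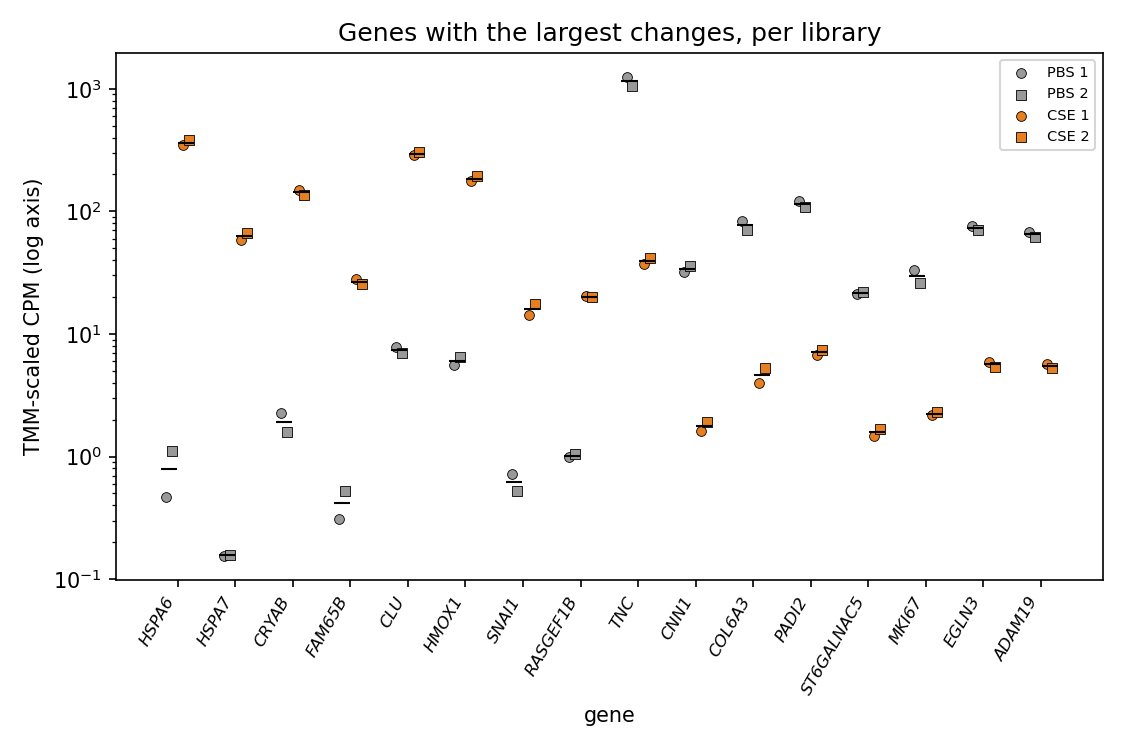
TMM-scaled CPM on a log axis of the 16 genes named for the largest changes at an average log2 CPM of at least 3, with a circle for replicate 1 and a square for replicate 2, grey for PBS and orange for CSE, and a horizontal bar at each group mean. For all 16 genes both CSE libraries lie on the same side of both PBS libraries, as for HSPA6 (means 0.785 and 363.5 CPM) and TNC (means 1153 and 39.5 CPM).

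Of the 34 gene lists tested, 18 passed camera at its preset correlation of 0.01, 8 of them upward and 10 downward. None passed camera with an estimated correlation (0 of 34, with 6 at an unadjusted p under 0.05). That form of the test has few degrees of freedom with 2 libraries per group, so hardly any list could pass it after adjustment. The heat shock list had an estimated correlation of 0.012, near the preset 0.01, and still an adjusted p of 0.137. Among the 18 lists past the preset, estimates ran from -0.162 for aryl hydrocarbon receptor targets to 0.385 for immediate early genes. Proteasome subunits (0.349) and TGF-beta response genes (0.289) were also well above 0.01. For such lists the preset p can be much too small. With so few degrees of freedom, the outcome with an estimated correlation does not decide whether correlation between genes accounts for the preset results. The fry test, which asks whether any shift is present within the list itself rather than against other genes, passed for 31 of 34 in a single direction and for 34 of 34 in either direction. Since 60.4% of all tested genes were called changed, almost any list could pass in either direction. These counts therefore do not set the lists apart from other genes. Counts of members that rose or fell adjusted over the list alone were the same as those over all tested genes for every tested list except the NRF2, cholesterol synthesis and ribosomal protein lists, whose counts are given with them.

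**Figure D3:**
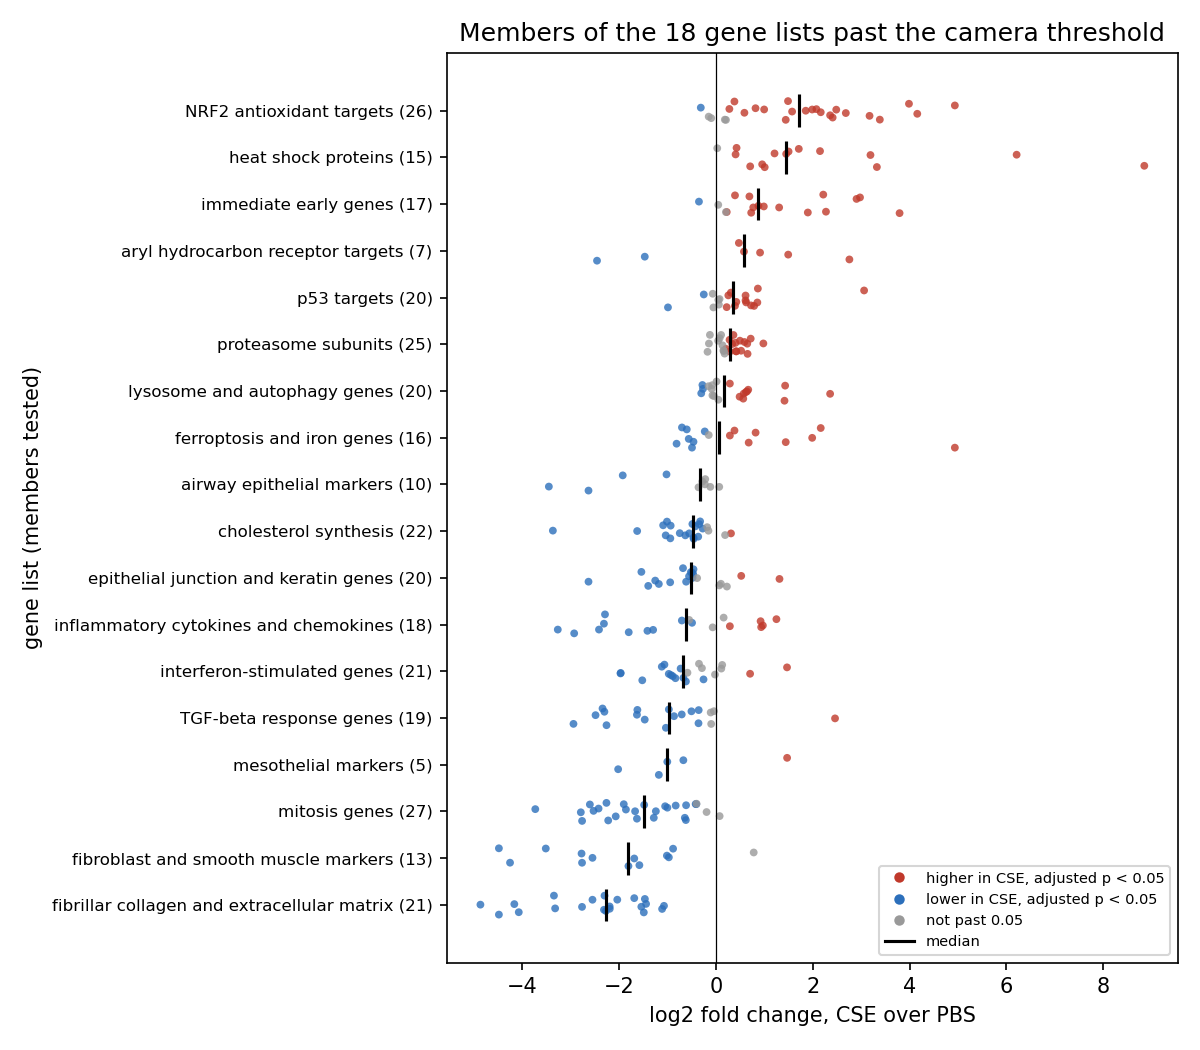
Log2 fold changes, CSE over PBS, of the tested members of the 18 gene lists past the camera threshold at its preset correlation, 1 point per gene, in red or blue where the gene was higher or lower in CSE at an adjusted p under 0.05 and in grey where it was not past it. Black bars are list medians, from 1.71 for the NRF2 targets to -2.27 for the fibrillar collagen and matrix list.

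Heat shock proteins, which refold or hold damaged proteins, rose almost as a whole list, with 14 of 15 members higher, 0 lower and 1 not past the test (median log2 1.45). HSPA1A rose 9.13-fold and its near-identical copy HSPA1B by log2 3.32 ± 0.10, values that cannot be separated with certainty. The abundant HSP90AA1 rose from 1965 ± 187 to 3948 ± 253 CPM. The list passed camera at an adjusted p of 3.98e-32, and had an adjusted p = 0.137 with an estimated correlation. NRF2 antioxidant targets, the genes that make and recycle glutathione, thioredoxin and quinone-reducing enzymes, rose in 21 of 26 cases, with 1 fall and 4 not past the test (23 and 1 adjusted over the list alone). OSGIN1 rose 10.4-fold, SRXN1, which repairs peroxiredoxins, by log2 2.41 ± 0.09, and TXNRD1, a thioredoxin reductase, from 830.5 ± 24.7 to 2470 ± 25.1 CPM, whereas NQO1 rose by log2 0.82 ± 0.08. AKR1C1 (log2 4.16 ± 0.09) and AKR1C2 (log2 2.48 ± 0.09) are near-identical copies. The NRF2 list median was 1.71 (camera adjusted p = 1.97e-33; adjusted p = 0.139 with an estimated correlation).

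Targets of the aryl hydrocarbon receptor, the sensor of polycyclic hydrocarbons, rose in 5 of 7 tested cases. CYP1A1, which oxidises such hydrocarbons, rose 6.75-fold to 140 ± 0.905 CPM, TIPARP rose 1.88-fold, CYP1B1 rose by log2 0.47 ± 0.08, and AHRR and NFE2L2 also rose. SLC7A5, an amino acid transporter, fell by 1.47 ± 0.09, and UGT1A6 fell, a call lost without CSE replicate 2 (adjusted p = 0.0505). The list passed camera at an adjusted p of 0.0412 (median 0.58), with an adjusted p = 0.325 with an estimated correlation, and over the other settings the camera adjusted p ranged from 0.0110 to 0.254, with 0.0887 without PBS replicate 1 and 0.0827 without PBS replicate 2. Of 5 tested metallothioneins, metal-binding proteins encoded by similar copies, MT1G, MT1X and MT1F rose, MT2A fell and 1 did not pass. MT1G went from 2 to 296 counts, a ratio of 130 with a 95% counting interval of 35.6 to 1080, and MT1X rose 3.22-fold. MT2A fell by 0.29 ± 0.08, a call lost without CSE replicate 1 (adjusted p = 0.165) and with library totals alone, and the MT1F call was lost whichever single library was left out (adjusted p of 0.094 and more). The metallothionein list did not pass camera (adjusted p = 0.0992, median 0.81), and its median ran from 0.292 to 0.985 over the other settings.

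The unfolded protein and integrated stress response list divided, with 9 of 23 members higher, 10 lower and 4 not past the test. ATF3 and PPP1R15A, a stress-induced transcription factor and the phosphatase subunit that restarts translation, rose 7.86-fold and 8.41-fold, and DDIT3, which encodes the stress factor CHOP, rose 4.16-fold, whereas ASNS, the asparagine synthetase, fell by 0.84 ± 0.10. The median of this list was -0.09 (0.09 with library totals alone) while its mean was 0.15 and camera pointed upward, without passing (adjusted p = 0.224). Immediate early genes, which respond within minutes to signals, were higher in 14 of 17 cases after 48 h. FOS rose 13.9-fold from 1.64 ± 0.0938 CPM, FOSL1 rose 3.72-fold, EGR1 alone fell, and 2 did not pass. The EGR1 call was lost without CSE replicate 1 (adjusted p = 0.120) and with library totals alone. The immediate early list passed camera (adjusted p = 6.70e-12, median 0.88), with an adjusted p = 0.278 with an estimated correlation.

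Proteasome subunits rose in 15 of 25 cases with 0 falls and 10 not past the test, among them PSMD12 at 1.97-fold, PSMC6 at 1.64-fold and PSMA3 at 1.56-fold (camera adjusted p = 0.00821, median 0.29; adjusted p = 0.567 with an estimated correlation). In the lysosome and autophagy list 10 of 20 genes rose, 3 fell and 7 did not pass. SQSTM1, the autophagy receptor p62 and also an NRF2 target, rose 5.12-fold to 2970 ± 111 CPM, and GABARAPL1 and MAP1LC3B, of the autophagosome membrane, rose 2.69-fold and 2.67-fold. HEXA, CTSD and LAMP2 fell by less than log2 0.31, calls lost without CSE replicate 2 for HEXA and LAMP2 (adjusted p = 0.0564 and 0.157) and without CSE replicate 1 for CTSD (0.174), and for all 3 with library totals alone. The lysosome list had a camera adjusted p of 0.00445 (median 0.17) and an adjusted p = 0.278 with an estimated correlation, and the camera adjusted p ranged from 0.000608 to 0.148 over the other settings, being above 0.05 without a low-count filter and with limma-voom. Iron and ferroptosis genes rose in 8 of 16 cases, fell in 7 and did not pass in 1. FTL and FTH1, the ferritin chains that store iron, rose 4.48-fold to 8227 ± 576 CPM and by log2 1.44 ± 0.10, SLC7A11, the cystine importer, rose 3.96-fold, and TFRC, the transferrin receptor, fell by 0.60 ± 0.09. Ferritin values may include reads of pseudogenes. The 4 members of the iron list that rose at least 2-fold, HMOX1, FTL, SLC7A11 and FTH1, are also on the NRF2 list. The iron list passed camera upward (adjusted p = 0.0022, median 0.07; adjusted p = 0.278 with an estimated correlation), but over the other settings the adjusted p ranged from 0.000388 to 0.650, and without the 10 most abundant genes, which include FTL and FTH1, it was 0.091 with a median of -0.19.

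Extracellular matrix genes fell without exception among the 21 tested, by at least 2-fold each. VCAN, a large proteoglycan, went from 677 ± 110 to 66.5 ± 1.88 CPM, FN1, fibronectin, fell by 1.47 ± 0.11 from 12280 ± 1819 CPM, and THBS1, thrombospondin, fell by 2.20 ± 0.09 from 7339 ± 464 CPM. The matrix list had a median of -2.27 (camera adjusted p = 5.03e-32; adjusted p = 0.137 with an estimated correlation). TGF-beta response genes fell in 15 of 19 cases and 3 did not pass. LTBP2 fell by 2.94 ± 0.09, TGFBI fell by 2.49 ± 0.09 to 524 ± 10.3 CPM, and the actin-binding TPM1 fell by 2.30 ± 0.08, whereas ID2, a helix-loop-helix inhibitor, rose by log2 2.46 ± 0.12. The TGF-beta list passed camera (adjusted p = 1.63e-13, median -0.97; adjusted p = 0.278 with an estimated correlation). Markers of fibroblasts and smooth muscle moved with these groups, with 12 of 13 tested markers lower, 0 higher and 1 not past the test. The lists overlap, since COL1A1, COL3A1, LUM and DCN are also on the matrix list and ACTA2 on the TGF-beta list. COL1A1, which epithelial cells in culture can also express, fell by 1.69 ± 0.08 from 167 ± 0.651 CPM, and COL3A1, at 108 and 116 counts in PBS and 5 and 6 in CSE, fell by 4.48 ± 0.30. The fibroblast list had a median of -1.81 (camera adjusted p = 1.68e-06; adjusted p = 0.207 with an estimated correlation). Matrix metalloproteinases and their inhibitors divided, with 6 of 12 higher, 5 lower and 1 not past the test. MMP10 rose from 4 to 142 counts, a ratio of 31.1 with a 95% counting interval of 11.9 to 116, and MMP1 rose by log2 1.54 ± 0.20 from a low level. The inhibitors TIMP3 and TIMP1 fell by 3.25 ± 0.09 and 0.97 ± 0.08 and MMP2, TIMP2 and MMP14 also fell. The metalloproteinase list did not pass camera, which pointed downward (adjusted p = 0.222) like the median of -0.02 (0.16 with library totals alone) and unlike the mean of 0.25.

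Mitotic genes fell in 24 of 27 cases, 0 rose and 3 did not pass. TOP2A, the topoisomerase of dividing cells, fell by 2.26 ± 0.12 from 36.0 ± 2.80 CPM, and CDC20, an activator of the anaphase-promoting complex, fell by 2.77 ± 0.17. The mitosis list had a median of -1.48 (camera adjusted p = 1.10e-10; adjusted p = 0.207 with an estimated correlation). Genes of G1/S and DNA replication went both ways, 7 higher, 12 lower and 5 not past the test among 24. RRM2 of ribonucleotide reductase fell by 1.71 ± 0.12, while SLBP, which binds histone mRNA, rose 1.49-fold and PCNA, the replication clamp, rose by log2 0.49 ± 0.09 (camera adjusted p = 0.397, median -0.27). Homologous recombination and Fanconi repair genes fell in 10 of 16 cases, with 0 rises and 6 not past the test, including BRIP1 and FANCD2, which fell by 1.38 ± 0.14 and 1.18 ± 0.14. The repair list missed the camera threshold (adjusted p = 0.0511, median -0.75) and passed it without CSE replicate 1 (0.0266) and in 3 other settings, within a range of 0.000911 to 0.129. Targets of p53 rose in 13 of 20 cases, 2 fell and 5 did not pass. The stress cytokine GDF15 rose 8.34-fold to 306 ± 33.9 CPM, the nuclease AEN 1.82-fold, the cell cycle inhibitor CDKN1A by log2 0.61 ± 0.08 and MDM2, which degrades p53, by log2 0.72 ± 0.08. TP53I3 and BAX fell, the former by 0.99 ± 0.09 and the latter with a call lost without CSE replicate 1 (adjusted p = 0.122), without CSE replicate 2 (0.0642) and with library totals alone. The p53 list passed camera (adjusted p = 0.00502, median 0.35; adjusted p = 0.278 with an estimated correlation). The senescence list, secreted factors and markers of arrested cells, had 7 higher, 9 lower and 3 not past the test among 19, with IGFBP3 and IGFBP5, binders of insulin-like growth factors, falling by 3.37 ± 0.09 and 3.49 ± 0.13 (camera adjusted p = 0.161, median -0.12, and 0.06 with library totals alone).

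Genes of epithelial junctions and keratins fell in 14 of 20 cases, CLDN4 and OCLN of tight junctions rose and 4 did not pass. KRT8, the most abundant keratin in PBS, went from 7466 ± 143 to 2830 ± 128 CPM, CLDN1 fell by 1.25 ± 0.08 and CDH1, E-cadherin, fell by 0.95 ± 0.09, whereas CLDN4 rose 2.48-fold. The junction list passed camera downward (adjusted p = 0.00158, median -0.51; adjusted p = 0.333 with an estimated correlation). Alveolar type 2 markers moved both ways, with SFTPB, NAPSA, ETV5, LAMP3 and SLC34A2 higher, ABCA3 and LPCAT1 lower and 2 not past the test among 9. Surfactant protein gene SFTPB rose 1.92-fold to 89.8 ± 9.89 CPM, and ABCA3, the lamellar body lipid transporter, fell by 0.97 ± 0.10. The LAMP3 call was lost without CSE replicate 1 (adjusted p = 0.0912) or CSE replicate 2 (0.0516) and that of SLC34A2 without PBS replicate 2 (0.428), CSE replicate 1 (0.148) or CSE replicate 2 (0.188). Type 1 markers rose for CLDN18, EMP2 and AQP4 and fell for PDPN, CAV1, CAV2, GPRC5A and TNNC1, with 5 of 13 not past the test. CLDN18, a lung claudin, rose 14.7-fold from 15 and 19 counts in PBS to 289 and 277 in CSE, while podoplanin, PDPN, fell by 1.47 ± 0.08, CAV1 of caveolae fell by 0.98 ± 0.07, and the TNNC1 call was lost without CSE replicate 1 (adjusted p = 0.0618). Neither alveolar list passed camera (adjusted p = 0.534 for type 2 with a median of 0.23, and 0.436 for type 1, whose median of -0.32 and downward test differed in sign from its mean of 0.07).

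Airway epithelial markers included 4 falls, 0 rises and 6 not past the test among 10. TP63, the basal cell transcription factor, fell by 3.45 ± 0.13 from 38.7 ± 2.76 CPM, the basal keratin KRT5 fell by 2.63 ± 0.31, and PIFO and CAPS of ciliated cells also fell. The airway list passed camera (adjusted p = 0.0159, median -0.32; adjusted p = 0.278 with an estimated correlation), with a range of 0.00872 to 0.110 over the other settings and 0.110 without a low-count filter. Over those settings its median ran from -0.619 to -0.142. Endothelial markers did not pass camera against the other genes (3 higher, 5 lower and 1 not past the test among 9, adjusted p = 0.543, median -1.05), and ESAM and EGFL7 are not restricted to vessels. ESAM, PROX1 and KDR rose, EGFL7 fell by 1.05 ± 0.15, and FLT1, PECAM1, VWF and CDH5 also fell. The calls of KDR, VWF and CDH5 were each lost without at least 1 library, KDR without PBS replicate 2 (adjusted p = 0.0558) or CSE replicate 1 (0.123), VWF without CSE replicate 2 (0.0658), and CDH5 without PBS replicate 1 (0.0769), CSE replicate 1 (0.0885) or CSE replicate 2 (0.0657). Leukocyte and macrophage markers MRC1, CD68, CSF1R and CD79A were higher in CSE, all 4 tested of 15 fixed. MRC1, CSF1R and CD79A passed the low-count filter only through the CSE libraries, so the filter itself favoured rises and a high median in this list. MRC1, the mannose receptor, went from 2 to 75 counts, a ratio of 32.9 with a 95% counting interval of 8.79 to 276, and CD68, a lysosomal protein found beyond leukocytes, rose 1.66-fold. PTPRC, the pan-leukocyte marker, had 0 counts in PBS and 4 and 7 in CSE. The CSF1R call was lost without either CSE library, although its log2 fold change of 2.62 stayed at 2.63 and 2.61. That of CD79A was lost without PBS replicate 2 (log2 1.82) or CSE replicate 2 (log2 1.91). The leukocyte list did not pass camera (adjusted p = 0.0669, median 2.36) except without CSE replicate 1 (0.0275) and in 2 other settings, within a range of 0.0094 to 0.125. Mesothelial markers KRT18, BNC1, MSLN and UPK3B fell and LRRN4 rose, with KRT18 also abundant in epithelium (a fall by 1.18 ± 0.09 from 3768 ± 126 CPM). UPK3B lost its call without CSE replicate 1 (adjusted p = 0.115). The mesothelial list had a camera adjusted p of 0.0468 (median -1.01; adjusted p = 0.336 with an estimated correlation), from 0.0272 to 0.254 over the other settings, among them 0.0622 without CSE replicate 1.

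Inflammatory cytokines and chemokines fell in 10 of 18 tested cases, 3 did not pass, and CXCL2, IL11, PTGS2, TSLP and CSF2 rose. IL1A, an alarmin, fell by 2.31 ± 0.13, the adhesion molecule ICAM1 fell by 1.42 ± 0.08 to 264 ± 14.8 CPM, the monocyte chemokine CCL2 fell by 2.29 ± 0.15, and IL6 went from 29 and 33 counts to 3 and 4. Calls were lost for IL11 without CSE replicate 2 (adjusted p = 0.132), for PTGS2 without CSE replicate 1 (0.0982) or CSE replicate 2 (0.103), for TSLP without PBS replicate 1 (0.0859) or either CSE library (0.0826 and 0.0941), and for CSF2 without PBS replicate 2 (0.0609) or either CSE library (0.0671 and 0.133). The cytokine list passed camera downward (adjusted p = 0.0159, median -0.63; adjusted p = 0.278 with an estimated correlation), with a range of 0.00734 to 0.059 over the other settings and the highest value with limma-voom. NF-kB feedback genes did not pass camera against the other genes (adjusted p = 0.369, median 0.04). The apoptosis inhibitor BIRC3 rose 2.07-fold, the mitochondrial superoxide dismutase SOD2 1.81-fold and TRAF1 1.80-fold, NFKBIE and NFKBIA also rose, IER3, NFKB1 and NFKB2 fell, and 4 of 12 did not pass. Without CSE replicate 1 the calls of NFKBIA, IER3 and NFKB2 were lost (adjusted p = 0.0852, 0.0673 and 0.098), without CSE replicate 2 those of NFKBIE, NFKBIA and NFKB1 (0.211, 0.238 and 0.0701), without PBS replicate 1 that of NFKBIA (0.111) and without PBS replicate 2 that of NFKBIE (0.0617). Those of NFKB1 and NFKB2 were also lost with library totals alone. Interferon-stimulated genes fell in 13 of 21 cases, ISG20 and RSAD2 rose and 6 did not pass. The antiviral sensors OAS3 and DDX58 fell by 1.52 ± 0.12 and 1.06 ± 0.09, IRF9, part of the interferon-activated factor, fell by 0.84 ± 0.10, and the RSAD2 call was lost without PBS replicate 2 (adjusted p = 0.156) or either CSE library (0.213 and 0.0623). The interferon list passed camera (adjusted p = 0.0327, median -0.67; adjusted p = 0.336 with an estimated correlation), with a range of 0.00113 to 0.0816 over the other settings and 0.0816 without PBS replicate 1. In the antigen presentation list TAPBP and CD74, chaperones of the peptide-loading steps, fell by 1.01 ± 0.08 and 0.93 ± 0.11 among 6 falls, HLA-E rose 1.52-fold as the only rise, and 6 of 13 did not pass (camera adjusted p = 0.222, median -0.27).

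Cholesterol synthesis genes fell in 18 of 22 cases, 1 rose and 3 did not pass (19 falls and 1 rise adjusted over the list alone). The cyclase LSS fell by 1.63 ± 0.08 and the reductase DHCR7 fell by 1.04 ± 0.07 on the log2 scale, and IDI1, an isomerase of the pathway, rose by log2 0.31 ± 0.08. The cholesterol list had a median of -0.48 (camera adjusted p = 4.48e-06; adjusted p = 0.207 with an estimated correlation). Fatty acid and lipid storage genes fell in 10 of 15 cases, PLIN2, PDK4, CPT1A and LPIN1 rose and 1 did not pass. PLIN2, which coats lipid droplets, rose 4.27-fold, PDK4, which limits pyruvate oxidation, rose 7.23-fold, and the desaturase SCD fell by 1.85 ± 0.09 from 753 ± 63.2 CPM. The fatty acid list missed the camera threshold (adjusted p = 0.0669, median -0.68) and passed it without PBS replicate 1 (0.0157), without PBS replicate 2 (0.00776) and in 2 other settings, within a range that reached 0.115. Hypoxia and glycolysis genes divided evenly, with 6 higher, 6 lower and 6 not past the test. Adrenomedullin, ADM, and NDRG1 rose 5.78-fold and 4.52-fold, while SLC2A1, the glucose transporter, fell by 1.06 ± 0.08 and LDHA, lactate dehydrogenase, fell by 0.99 ± 0.08 (camera adjusted p = 0.645, median -0.13, and 0.05 with library totals alone). Nuclear genes of oxidative phosphorylation fell in 11 of 26 cases, NDUFB5, NDUFS3 and SDHB rose and 12 did not pass, with a fall of the complex I subunit NDUFV1 at log2 -0.86 ± 0.09 (camera adjusted p = 0.224, from 0.0142 without a low-count filter to 0.433; median -0.15, and 0.03 with library totals alone). The NDUFS3 and SDHB calls were each lost without PBS replicate 2 (adjusted p = 0.198 and 0.385), CSE replicate 1 (0.180 and 0.239) or CSE replicate 2 (0.135 and 0.117). Ribosomal protein genes fell in 11 of 30 cases with 0 rises and 19 not past the test (6 falls and 0 rises adjusted over the list alone), RPL3 by the most at log2 -0.49 ± 0.08, and their median of -0.15 became 0.03 with library totals alone (camera adjusted p = 0.222, from 0.00146 without a low-count filter to 0.499, and 0.0401 with limma-voom). All 86 ribosomal protein genes together took 3.04% and 2.97% of the counts in PBS and 3.01% and 3.10% in CSE. The list of mitochondrially encoded genes was not analysed here, and all CPM and shares are of counts without these genes.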

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

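All of the alternative settings but the gene families were chosen before the data were examined. The count of changed genes stayed within 1.5 times that of 8671, and without the block it ran from 5946 without CSE replicate 1 to 8944 without PBS replicate 2, with 6938 by DESeq2 and 7755 of 20330 genes without a low-count filter; at least 2-fold changes numbered from 2132 with the CPM filter to 2677. Without CSE replicate 1, 5884 of the 8671 genes kept their call, and by DESeq2 6923. The labels do not say whether same-numbered libraries of the groups belong together. Their deviations correlated at 0.0076 over all tested genes, many of them with few counts, which does not exclude a pairing. With the replicate block, 9148 genes changed, and the mesothelial list (camera adjusted p = 0.0515) passed its threshold no more while the fatty acid list (0.0446) did. Of 202 named genes, 169 kept their call under every setting in which they were tested and 32 lost it in at least 1. Each gene that lost its call did so in some fit that left out 1 library, and EPCAM gained a call. Many of these genes were named for large changes or small p, so the share that kept a call is not that of all genes. DESeq2, which gives gene results only, dropped the calls of CD79A, MT1F, IL11, TSLP, CSF2, NFKBIE, NFKBIA, RSAD2, LAMP3, SLC34A2, VWF, CDH5, UPK3B, NDUFS3 and SDHB. None turned its direction. Of the lists, the test direction of the unfolded protein list turned without a low-count filter (median -0.11, adjusted p = 0.519) and with limma-voom (median -0.086, adjusted p = 0.824), within a range of 0.115 to 0.824, and that of the endothelial list with the CPM filter (median -0.32, adjusted p = 0.997), within 0.158 to 0.997. None of these passed, and the cause was not tested. In fits that leave 1 library in a group, that library is assumed to vary like the others. Without a CSE library the spread comes from the PBS pair alone, which differed more (chi-square per degree of freedom 9.31 against 3.45). A call lost there need not mean a smaller change. PTGS2 stayed at log2 0.29 and 0.28 without CSE replicate 1 and 2, against 0.29 in the main fit. IL11, by contrast, went from 0.93 to 0.69 without CSE replicate 2. At these totals and with 2 libraries per group, the simulation recovered 61.2% of 1.5-fold changes and 97% of 4-fold changes. It changed a far smaller share of the genes than was called in the data, so recovery in the real comparison may differ.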

Other observations

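The gene families in this part, and the tests on fibroblast transcripts, were chosen after the results were seen; the tests on detected genes and on zinc finger genes were set before their results were seen, for patterns noticed in the data. Of 225 families of at least 8 tested genes with a common symbol prefix, 16 passed camera at its preset correlation, 6 upward and 10 downward, and 0 with an estimated correlation, where each had an adjusted p = 0.916 and 4 families had an unadjusted p under 0.05. With 2 libraries per group that second form has too few degrees of freedom for a family to be likely to pass over 225, whatever its correlation. Histone genes of the older HIST symbols, packaging proteins of chromatin, rose in 15 of 17 cases with 0 falls (median 2.23, camera adjusted p = 0.00178), among them HIST1H2BK from 10.6 ± 0.334 CPM (SD, n = 2) by log2 1.84 ± 0.10, HIST1H1C by log2 2.10 and HIST2H2BE by log2 1.53, although reads can be shared between histone copies. Autophagy genes with the prefix ATG rose in 14 of 18 cases with 2 falls (median 0.49, adjusted p = 0.0107), among them ATG2A and ATG14 at log2 1.23 and 1.20.

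Families that passed camera downward included tubulins, myosins, integrins and cadherins. Genes with the prefix TUBB, beta-tubulins, fell in 7 of 8 cases (median -1.30, adjusted p = 3.43e-06), with TUBB6 and TUBB3 at log2 -1.68 and -1.56, and myosins in 13 of 20 with 0 rises (median -0.47, adjusted p = 0.0254). Genes with the prefix ITGB, integrin beta chains and a few binding partners, fell in 6 of 9 cases with 0 rises (median -1.10, adjusted p = 3.64e-07), with ITGB3 and ITGB6 at -2.39 and -1.74 and the abundant ITGB1 at -1.38, integrin alpha chains in 6 of 10 (median -0.66) and cadherins in 9 of 12 (median -1.46), CDH2 at -1.66 and CDH11 at -2.69. Collagens fell in 22 of 28 cases (median -1.35), with the basement membrane chain COL4A1 at -2.34 and the hemidesmosome collagen COL17A1 at -2.56, and keratins in 12 of 17 (median -1.18), with KRT80 and KRT17 at -2.21 and -1.79. Also lower were the aldehyde dehydrogenases (9 of 14, ALDH1B1 at -1.52 and ALDH1A3 at -1.33), the GALNT glycosyltransferases (8 of 11) and the semaphorins (10 of 15). Higher were HSPA chaperones (12 of 14), aldo-keto reductases (4 of 8), KLHL genes (12 of 27) and ZNF genes (252 of 497). Of all 14359 tested genes, 4433 were higher and 4238 lower. The 4 aldo-keto reductases that rose are all on the NRF2 list and several HSPA genes are on the heat shock list, so these families are not separate results. Without a low-count filter the median was -0.15 for keratins (adjusted p = 0.186, call lost), -0.97 for cadherins (0.226, call lost), -0.68 for ITGB genes, 0.56 for KLHL genes (0.0787, call lost) and 2.88 for aldo-keto reductases. Calls were lost in some settings for AKR, ALDH, CDH, ITGA, KLHL, KRT and SEMA, including without 1 library for ALDH (adjusted p = 0.053 without PBS replicate 1 and 0.0699 without CSE replicate 2) and SEMA (0.0791 without PBS replicate 2, 0.0644 without CSE replicate 1 and 0.058 without CSE replicate 2).

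The CSE libraries held on average 1183.5 more detected genes than the PBS libraries, at nearly equal totals. A smaller share of counts in the most abundant genes could leave more reads for rare ones, but with the 100 most abundant genes removed and all libraries thinned to 15589910 counts the excess was 1134.5, against a largest difference of 293 between replicates, which argues against that as the whole cause. Read-through from neighbouring genes was examined by position. Genes that overlap an expressed gene were left out, among them 95 that were newly at 10 counts or more in both CSE libraries. Read-through at those was not examined. The other genes newly at that level had an expressed gene whose 3′ end faced them within 10 kb in 20.3% of 449 cases. Among 7990 other low genes the share was 9.17% (odds ratio 2.52, 95% interval 1.95 to 3.22, Fisher's exact p = 4.37e-12). The odds ratio for a facing 5′ end was 3.29 (2.56 to 4.21), and the log odds ratios differed by -0.269 (-0.611 to 0.0729). The rule set beforehand counted against read-through if the odds ratio for a 3′ end was not the higher, and it was not. The interval of the difference spans both signs, so read-through at some of these genes cannot be told apart from wider activity of the same regions. A response of the cells to CSE is also open and was not tested apart from these.

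The fall of matrix transcripts came with a fall of fibroblast markers, and fewer contaminating fibroblasts in the CSE cultures might explain both. For the abundant matrix genes the values argue against it: COL1A2, COL3A1, DCN and LUM, abundant in fibroblasts, together lost 14.2 CPM, 0.147% of the 9700 CPM lost by TNC, VCAN and FN1. Of that loss FN1 made up 7964 CPM, TNC 1121 and VCAN 615.3. These CPM were scaled before the low-count filter and differ slightly from those given above. COL1A1 was left out of the sum and fell from 166.5 to 51.7 CPM, still a smaller loss than that of TNC, VCAN or FN1. The low-level markers do not settle it: COL1A2, COL3A1, PDGFRA, PDGFRB, THY1, LUM, DCN and FAP fell by unequal folds (log2 -4.48 to -1.58; Cochran Q 64.4, chi-square p = 2e-11, with the SE of each gene taken as its error), which a loss alone forbids only if no other cells express them, and that was not measured. The SE can be too small at low counts, so Q may be too large and its p too small. For these low-level markers a loss of fibroblasts, a change within them and a change within the epithelial cells all stay open.

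Zinc finger genes (ZNF prefix) were higher in CSE in 252 of 497 cases and lower in 33, with a median log2 fold change of 0.40 (ZNF473 at 2.25, ZNF778 at 2.62 and ZNF468 at 1.76). Low expression and transcript length are unlikely to account for this, since 0 of 10000 random sets matched on both reached that median, the highest at 0.153. Reads shared among the copies clustered on chromosome 19 could inflate the shift, but the 251 genes elsewhere had a median of 0.252 (95% interval 0.177 to 0.321), against 0.524 (0.435 to 0.587) for the 246 on that chromosome. These intervals come from resampling genes, so they measure the spread between genes of the same 4 libraries and not that between libraries. The excess of the ZNF median over that of all genes (at least 0.381 over the other scalings) decides nothing about scaling, since a factor per library moves all genes alike. A response of this family to CSE stays open as a hypothesis, found on the same data and not tested. The ZNF genes did not pass camera with an estimated correlation (adjusted p = 0.916), a form that hardly any family could pass with 2 libraries per group.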
